A study of Mus musculus with 30 samples.

How the data were processed

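The samples are libraries of mouse brain and spinal cord RNA sequenced on an Illumina instrument, per the series' design text. The labels give 30 samples in 10 groups of 3, and all groups were taken from the labels' titles. The analysed tables come from 18 of them: control and conditional Nova2 knockout (cKO) neurons sorted from Emx1-Cre and Gad2-Cre cortex at embryonic day 18.5, and control and cKO Purkinje tissue of Pcp2-Cre mice dissected at postnatal day 28, with 3 samples per group. All of these were C57BL/6J mice with ribosomal RNA removed, per the labels. The other 12 samples, in 4 groups (cortex without Nova2 and Ptbp2, poly(A)-selected cortex with and without Nova2, and wild-type spinal cord), were not analysed here. The labels do not say whether the 3 samples of a group came from separate animals, so the authors' FDR may in part measure technical spread.

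The authors quantified splicing with Quantas on mouse build mm10, per the labels, and the submitters' processing notes name kallisto and edgeR, which the authors used in a role that is not given in the sources used here. The aligner, versions, trimming and strandedness are likewise not given in the sources used here. Each deposited table holds, per the file headers, 1 inclusion level per group, a fraction from 0 to 1 which the authors name an inclusion rate and which is read here as the share of an event's RNA with the alternative region. The difference of the levels is group 1 minus group 2, which was tested on every event within 3e-08. Per the file headers each event also has the authors' p-value and FDR, with no FDR above 0.05, and no listed difference is below 0.1 in size. The coverage of an event, a signal whose definition is not given in the sources used here, is deposited as 1 value for the comparison, never below 20. Inclusion levels are the authors' pooled values, with no value per library, so no test across libraries was possible, and sample depth is unknown. Such filtering keeps events with large differences, which makes correlations and shares among listed events describe those events only. Deposited lists of genome intervals with the same event names were used only for positions.

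The labels name the control first for the Emx1-Cre and Gad2-Cre tables, and the Emx1-Cre group first for the table of controls. The control levels were the same in the table of controls and the matching cKO table at all 307 and all 323 shared events, within 1e-08. For the Purkinje table no order is named, and its groups are called 1 and 2. Event types were cassette exons, tandem cassettes, retained introns, mutually exclusive exons and alternative 5' and 3' splice sites. For the latter types the direction is that of the isoform the authors name first, which carries no order of inclusion.

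Chosen before the data were examined were the gene lists, the naming rule, the alternatives and these tests: the share of each direction in a table, the shared events of pairs of tables with their correlations, the share of retained introns, the size of shared and unshared events, YCAY by direction and the gene lists. Added after the tables had been seen were the comparison of directions between tables, the exchange within control levels, the difference of differences, the shares that moved toward the other class and their comparison, the events in 3 tables, the directions of introns listed in both cortical tables, the YCAY comparison with exons that differed only between controls, and the exon length classes. The share of events in each direction was tested against 50% with a two-sided exact binomial test, with Clopper-Pearson intervals at 95%, and Benjamini-Hochberg adjustment over the 9 tests of a table. Shares were compared between tables with Fisher's exact test, adjusted over 42 tests. Events were matched between tables by their identifier. The directions of shared events were compared with Fisher's exact test over 6 pairs of tables. As a second reference, differences of the second table were exchanged 10000 times within 5 classes of control level, since a level near 0 or 1 can move only one way. For pairs with the Purkinje table, the classes were those of its group 1 level, which is not known to be the control. Pearson's and Spearman's coefficients had 10000 permutations, and means had 100000. Intervals and tests over events cover counting error only and treat overlapping events of a gene as separate, which is why each main share was repeated with 1 event per gene, the one with the largest difference.

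To compare the size of a change between the cortical tables, the spread of each difference was derived from the authors' p-value as if it came from a normal test, and the difference of differences was tested with adjustment over 823 events. For events listed in opposite directions its outcome is largely fixed by their selection. This step was tested on simulated data for 823 events: with 200 events changed by 0.3, it recovered 69.0% of them and called 0.642% of the unchanged. The simulated counts held counting error only, and their p-values came from the normal form that the step assumes. No threshold of listing was applied to them. These rates may therefore not hold for the authors' p-values. For tables that share controls, unchanged groups were simulated 200 times against the same controls, over listed events only and with counting error only. Adjustment over a list alone was not made, as all listed events had passed the authors' FDR.

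Named events were set by a rule: for each table the 6 events with the largest absolute difference in each direction, 1 per gene; for each gene list the 2 largest, 1 per gene; for shared events the 6 with the largest summed difference in the same direction and up to 6 in opposite directions; and Nova2. In the Purkinje table, 1 event that the rule names is not reported here. The 10 lists were written from textbook knowledge, and the list of earlier NOVA targets was recalled from published work, not taken from these tables. The list of markers of other cell types also holds Pcp2, Calb1, Slc17a6 and Slc17a7, which mark some of the analysed classes themselves. Lists were compared between tables with Fisher's exact test of list genes against the other genes of each table. Benjamini-Hochberg adjustment was over the 10 lists of each pair of tables. Genes in both tables, such as the 426 in both cortical cKO tables, count on both sides as if they were independent.

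Exons were set against GENCODE release M21, whose build is that of mm10. Of the cassette exons 60.4% in the Emx1-Cre, 60.4% in the Gad2-Cre and 61.1% in the Purkinje table equal a GENCODE exon, and both ends of all retained introns are GENCODE exon ends. YCAY was counted per 100 nt in cassette exons that lie within a GENCODE exon, with 3 nt trimmed from each end and at least 10 nt left, in the transcripts' sequence. This covered 82.0%, 81.5% and 84.0% of exons. The planned search of flanking introns was not made, because no genome sequence was used here. Microexons are exons of at most 27 nt.

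The alternatives were an absolute difference of at least 0.2, an FDR of at most 0.01, a coverage of at least 50, 1 event per gene, cassette exons only, and matching of events by gene or by at least 50% reciprocal overlap. Chosen after seeing the data were YCAY counts in exons equal to a GENCODE exon and in exons of at least 20 nt after trimming, and 1 exon per gene for exon length. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.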

Results

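Nova2 encodes a neuronal RNA-binding protein that controls alternative splicing, and the series compares RNA from several classes of mouse neuron with and without it. The labels list 30 samples in 10 groups of 3. The splicing tables analysed here cover 18 samples in 6 groups, and the other 12 samples, in 4 groups, were not analysed here. Cortical neurons were sorted at embryonic day 18.5 from Emx1-Cre mice, whose Cre is taken here to mark excitatory neurons, and from Gad2-Cre mice, whose Cre is taken to mark inhibitory neurons. The purity of each sort was not tested, so a difference between these classes may in part reflect other cells. Purkinje tissue was dissected at postnatal day 28 from Pcp2-Cre mice, whose Cre marks Purkinje cells of the cerebellum. Each class had a control group and a conditional Nova2 knockout group, written cKO from here on. Each of 4 tables listed alternative splicing events that passed the authors' thresholds in 1 comparison. An inclusion level is the fraction of an event's RNA that contains the alternative region, from 0 to 1. The tables hold 1 pooled level per group, so no value of a single event has a replicate error, and the depth of each library is not known.

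The Emx1-Cre table listed 2682 events in 1043 genes, that of Gad2-Cre neurons listed 1970 in 879, that of Purkinje tissue 603 in 253, and that of Emx1-Cre against Gad2-Cre controls 1236 in 551. The median coverage of an event was 71, 64.0, 88.5 and 52 in these tables, and its lowest value was 20 in each. Nova2 itself had 0 listed events in each, so its own loss was not visible in them. Coordinates are on mouse build mm10 and counted from 1, and exon annotations are those of GENCODE release M21.

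In excitatory cortical neurons, exons that controls almost never used became the main form in the cKO. An exon of Lmtk3 (ENSMUSG00000062044), a kinase of the lemur family, rose from an inclusion level of 0.0189 in controls to 0.942 in cKO in the authors' deposited table (FDR 6.7e-55, coverage 133). It is a coding exon of 109 nt on chromosome 7, from 45787646 to 45787754. An exon of Glra2, a glycine receptor subunit, rose from 0.000257 to 0.854 in the authors' deposited table. This region of 244 nt, on chromosome X from 165325680 to 165325923, is not a GENCODE exon and lies outside annotated coding sequence. Tandem exons of Ank2, which links membrane proteins to the spectrin skeleton, rose from 0.105 to 0.926 by the authors' value, and those of Dab1, an adaptor of reelin signalling, rose from 0.00769 to 0.822. In Dlg3, a scaffold of glutamate synapses, the first-named of the mutually exclusive isoforms rose from 0.0354 to 0.910 by the authors' value, and in Atp11b from 0.151 to 0.943.

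Other exons were nearly constant in excitatory controls and lost in the cKO. The authors' deposited table gave tandem exons of Nrcam, a neuronal cell adhesion molecule, at 0.963 in controls and 0.0752 in cKO, with an FDR of 5.09e-60. A coding exon of 75 nt in Aff3, on chromosome 1 from 38538927 to 38539001, fell from 0.932 to 0.0756 in the authors' deposited table. An exon of 58 nt in Ccdc64, a dynein adaptor, fell from 0.905 to 0.0479 by the authors' value. Tandem exons of Epb4.1, a spectrin-actin linker, fell from 0.966 to 0.0617, again the authors' value, at a coverage of only 22.3. A coding exon of 45 nt in Nav2 fell from 1 to 0.152 in the authors' deposited table at a coverage of 28. The first-named mutually exclusive isoform of Lmtk3 fell from 0.970 to 0.0449. That event spans the Lmtk3 exon that rose, so both may reflect 1 change.

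Genes of synapses, the cytoskeleton and splicing itself were listed in the Emx1-Cre table. Of 40 synaptic adhesion genes, 18 had a listed event; the largest event of the gene was higher in cKO in 7 and lower in 11, among them Nrcam and Clstn1, a calsyntenin whose tandem exons fell from 0.958 to 0.134 by the authors' value. Of 46 glutamate synapse genes, 16 were listed, 10 higher and 6 lower; tandem exons of the adaptor Sorbs2 fell from 0.875 to 0.0559 in the authors' deposited table. Of 26 inhibitory synapse genes, 5 were listed, 4 higher and 1 lower; a coding exon of gephyrin, Gphn, on chromosome 12 from 78493950 to 78494057, rose from 0.180 to 0.881 by the authors' value. Of 65 ion channel genes, 10 were listed, 5 in each direction. A coding exon of the calcium channel Cacna1e rose from 0.372 to 0.968 by the authors' value, and a 12 nt coding exon of Cacna1b, on chromosome 2 from 24656711 to 24656722, fell from 0.540 to 0.00667.

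Of 54 cytoskeleton genes, 20 were listed, 7 higher and 13 lower. Of 57 axon guidance and migration genes, 12 were listed, 4 higher and 8 lower; tandem exons of the netrin receptor gene Neo1 rose from 0.267 to 0.977 in the authors' deposited table. Of 63 presynaptic and trafficking genes, 22 were listed, 8 higher and 14 lower, such as Epn1, which rose to 0.807, and the active zone gene Erc2, whose exon of 24 nt fell from 0.672 to 0.203, both the authors' values. Of 83 RNA-binding and splicing genes, 26 were listed, 13 in each direction. A 32 nt region of Rbfox2 fell from 0.868 to 0.451 by the authors' value, at a coverage of 42.6. This region is not a GENCODE exon and lies outside annotated coding sequence. Tandem exons of Hnrnpd fell from 0.893 to 0.545 in the authors' deposited table. Of 29 genes described as NOVA targets in earlier work, 22 were listed, 10 higher and 12 lower. Of 36 marker genes of other cell types, 1 was listed, the astrocyte glutamate transporter Slc1a2, whose exon rose from 0.0594 to 0.309 by the authors' value.

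Across the Emx1-Cre table, cassette exons went down about as often as up. Of 912 cassette events, 484 were lower in cKO (53.1%) and 428 higher, and a two-sided exact binomial test against 50% gave p = 0.0685 (Benjamini-Hochberg adjusted over 9 tests in the table, 0.123). Retained introns went mostly up: 250 of 297 were higher in cKO (84.2%, exact binomial p = 1.32e-34, adjusted 1.19e-33), and 205 of 250 were with 1 event per gene (82.0%). Over all types, 1383 of 2682 events were lower (51.6%, exact binomial p = 0.109); with 1 event per gene the share was 48.9% (p = 0.496), on the other side of 50%, and among differences of at least 0.2 it was 53.3%, which passed (p = 0.014). In this and the other tables such a share over all types also counts mutually exclusive exons and splice sites, for which it depends on the isoform named first, so it does not measure a loss of exons. Events of the same gene can share exons, so the tests over events count some changes more than once.

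Inhibitory cortical neurons without Nova2 lost more exons than they gained. In Erbb4, the neuregulin receptor of interneurons, a coding exon of 75 nt on chromosome 1 from 68290243 to 68290317 rose from 0.170 in controls to 0.918 in cKO in the authors' deposited table (FDR 3.65e-244, coverage 730). Tandem exons of Sorbs2 rose from 0.0272 to 0.811 by the authors' value, at another position than those that fell in excitatory neurons. In Adam22, a receptor for the synaptic protein LGI1, a 5' splice site isoform rose from 0.08 to 0.861 while a mutually exclusive isoform fell from 0.922 to 0.135, both the authors' values. Splice site isoforms also rose in Rasal2, a Ras GTPase-activating protein, from 0.0274 to 0.742, in Tex2 from 0.132 to 0.847, and in the chromatin remodelling gene Smarcc2 from 0.104 to 0.794, all in the authors' deposited table.

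Among exons that fell in the Gad2-Cre cKO, tandem exons of Myo9a, an unconventional myosin, went from 1 to 0.171 in the authors' deposited table. The Ccdc64 exon that fell in excitatory neurons fell here too, from 0.864 to 0.137 by the authors' value. Tandem exons of Actl6b, a neuronal subunit of the BAF chromatin complex, fell from 0.909 to 0.195 by the authors' value, and a 5' splice site isoform of the autophagy protease gene Atg4a fell from 0.897 to 0.150. An exon of 110 nt in Hfm1 fell from 1 to 0.0909 in the authors' deposited table, at the lowest coverage listed, 20.

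The same groups of genes were listed in inhibitory neurons. Of 40 adhesion genes, 16 were listed, 6 higher and 10 lower; Clstn1 fell from 0.981 to 0.384, and an exon of the receptor phosphatase Ptprs rose from 0.221 to 0.808, both the authors' values. Of 46 glutamate synapse genes, 15 were listed, 9 higher and 6 lower, with an exon of the kainate receptor Grik2 falling from 0.688 to 0.101 by the authors' value. Of 26 inhibitory synapse genes, 4 were listed, and all 4 were higher by their largest event; the Gphn exon rose from 0.0517 to 0.693 in the authors' deposited table. Of 65 ion channel genes, 10 were listed, 5 in each direction: an 18 nt exon of Cacna2d3 fell from 0.670 to 0.123, and an isoform of the potassium channel Kcnc2 fell from 0.639 to 0.0435, both the authors' values. Of 63 presynaptic genes, 16 were listed, 4 higher and 12 lower, such as a 36 nt exon of Cask that fell from 0.879 to 0.190 in the authors' deposited table.

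Of 54 cytoskeleton genes, 22 were listed in the Gad2-Cre table, 6 higher and 16 lower; an isoform of Ank3, the ankyrin of the axon initial segment, rose from 0.242 to 0.833 by the authors' value. Of 57 axon guidance genes, 11 were listed, 5 higher and 6 lower, Neo1 among the higher ones. Of 83 RNA-binding genes, 27 were listed, 18 higher and 9 lower. A 43 nt coding exon of Rbfox2 rose from 0.130 to 0.427, at another position than the region that fell in excitatory neurons. An isoform of Elavl2 rose from 0.0235 to 0.319, both in the authors' deposited table. Of the 29 earlier NOVA targets, 18 were listed, 5 higher and 13 lower. None of the 36 markers of other cell types was listed (0 genes).

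In inhibitory neurons, 463 of 726 cassette events were lower in cKO (63.8%, exact binomial p = 1.07e-13, adjusted 3.2e-13), as were 294 of 426 tandem cassettes (69.0%, p = 2.86e-15, adjusted 2.57e-14). Retained introns again went up, 177 of 242 (73.1%, exact binomial p = 3.64e-13, adjusted 8.18e-13). With 1 cassette event per gene, 257 of 416 genes were lower (61.8%, exact binomial p = 1.78e-06). Over all types, 1154 of 1970 events were lower (58.6%, exact binomial p = 2.72e-14). Of the 1970, however, 489 are mutually exclusive exons, whose direction depends on the isoform named first. With 1 event per gene the share over all types was 51.9% and did not pass (exact binomial p = 0.28). The cassette share differed between the tables, 53.1% lower in excitatory against 63.8% in inhibitory neurons (Fisher's exact test, p = 1.46e-05, adjusted over 42 such tests 4.38e-05; with 1 event per gene p = 0.00199, adjusted 0.00491). So did that of retained introns (84.2% against 73.1% higher, Fisher's exact test, p = 0.00194, adjusted 0.00491), though not with 1 event per gene (82.0% against 73.6%, p = 0.0385, adjusted 0.0647). Events listed in both tables count on both sides of these tests as if they were independent.

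**Figure D1:**
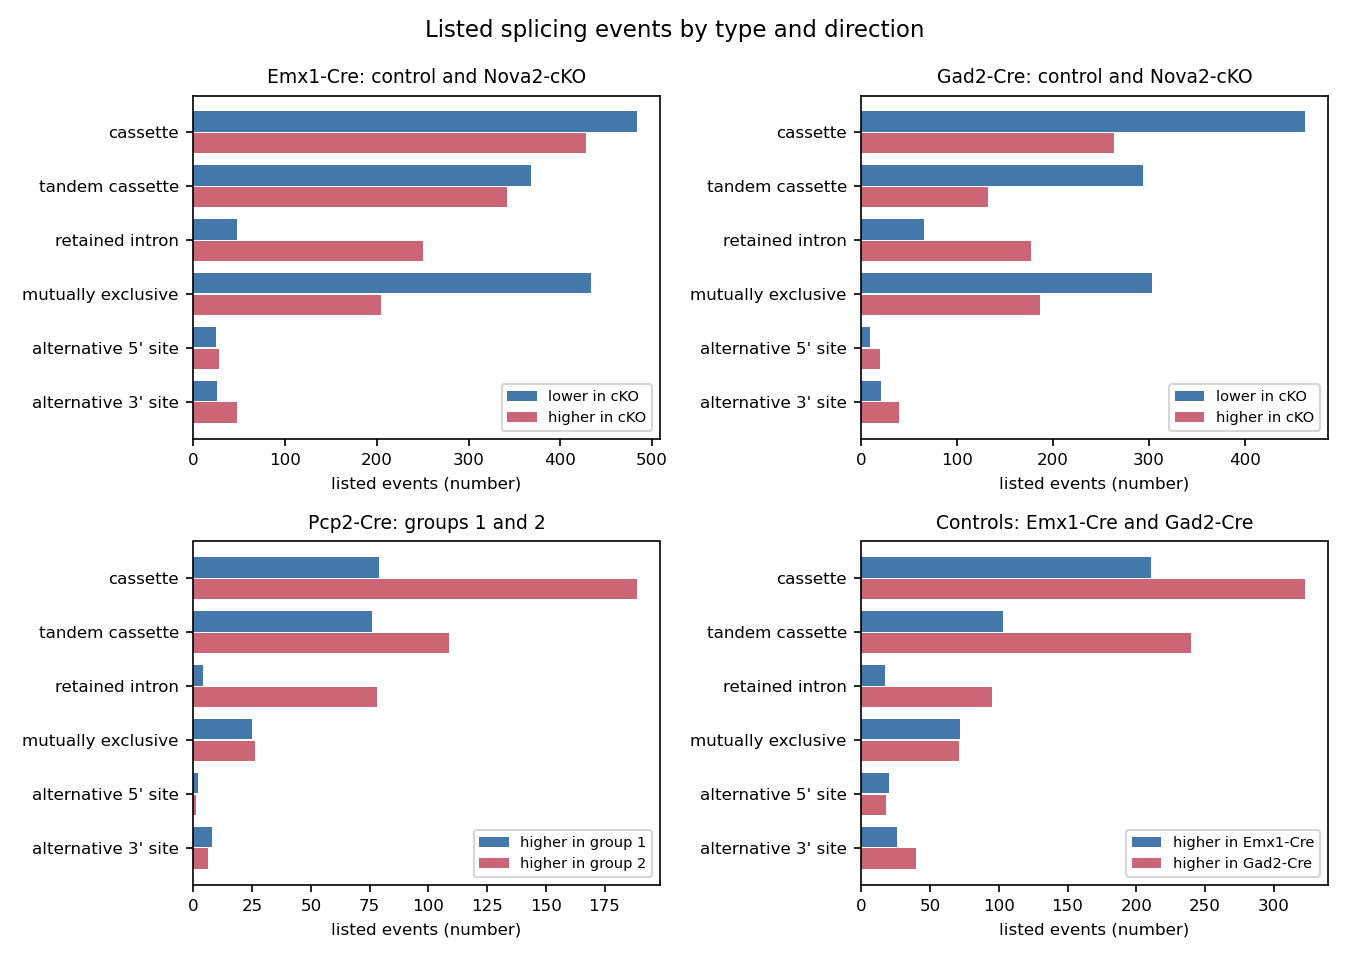
Number of listed splicing events by type (vertical axis) in each of the 4 tables, split by direction of the inclusion difference (bars, horizontal axis from 0). Retained introns are mostly higher in cKO in both cortical tables (250 of 297 and 177 of 242), and cassette exons are mostly lower in the Gad2-Cre cKO (463 of 726); for mutually exclusive exons and splice sites the direction is that of the isoform named first.

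Excitatory and inhibitory neurons shared a large set of events, and these moved the same way. In Lmtk3, the mutually exclusive isoform fell from 0.970 to 0.0449 in excitatory and from 0.988 to 0.322 in inhibitory neurons by the authors' values. The tandem exons of Myo9a fell from 0.793 to 0.0730 and from 1 to 0.171, and the Gphn exon rose from 0.180 to 0.881 and from 0.0517 to 0.693, again the authors' values. The tables shared 823 events in 355 genes, which was 30.7% of the Emx1-Cre and 41.8% of the Gad2-Cre table. Of these, 802 had the same direction (97.4%), 342 higher and 460 lower in both cKO groups.

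The association of directions was beyond chance (Fisher's exact test, p = 5.32e-205, adjusted to 3.19e-204 over the 6 pairs of tables). Exchanging Gad2-Cre values among events of like control level left 69.1% in that direction (95% of draws from 66.6% to 71.5%). Across these events, which are not independent replicates, the differences had a Pearson r of 0.925 and a Spearman rho of 0.917; permutation p was 0.0001 for both, the smallest that the permutations can give (adjusted 0.00012). Since no difference under 0.1 in size is listed, both coefficients describe listed events only.

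Events listed in both tables had larger differences than the others, which the listing itself favours, since a larger difference passes the authors' thresholds in both tables more readily. The mean absolute difference was 0.305 ± 0.182 (SD) over the 823 shared and 0.227 ± 0.126 over the 1859 unshared events of the Emx1-Cre table. In the Gad2-Cre table it was 0.288 ± 0.155 over the shared and 0.211 ± 0.107 over 1147 unshared events. Both differences gave a permutation p of 1e-05, the smallest that 100000 permutations can give; in cassettes alone, the Emx1-Cre difference was 0.127 in place of 0.0773. The shared events were also better covered, with a median of 107 against 54 in the Emx1-Cre and 86.2 against 48 in the Gad2-Cre table. Of 320 shared cassettes, 199 fell in excitatory and 201 in inhibitory neurons. Among cassettes listed in 1 table only, 285 of 592 fell in the Emx1-Cre table and 262 of 406 in the Gad2-Cre table.

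In a few genes the classes changed in opposite directions. A 46 nt exon of Uggt2, a glycoprotein-folding sensor, on chromosome 14 from 119032742 to 119032787, fell from 0.864 to 0.492 in excitatory neurons and rose from 0.363 to 0.652 in inhibitory neurons in the authors' deposited tables. The retained intron of Tmem214 rose from 0.274 to 0.496 in the former and fell from 0.696 to 0.426 in the latter, both the authors' values. An 18 nt coding exon of Adgrl3, a latrophilin adhesion receptor, on chromosome 5 from 81792361 to 81792378, rose from 0.439 to 0.650 and fell from 0.798 to 0.543 by the authors' values. The first-named isoform of the zinc finger gene Zfp516 fell from 0.8 to 0.513 and rose from 0.476 to 0.578, again the authors' values. In all, 21 events in 11 genes had opposite directions. Of these, 19 were also listed between the controls, and in all 19 each class moved toward the control level of the other. Chance values of the shared controls would also give that pattern. In a test of the difference of differences, with spreads taken from the authors' p-values, 106 of 823 events in 63 genes differed after adjustment over the 823. The 21 opposite events are among them, which their selection largely fixes, since each had passed the authors' thresholds in both tables. The difference was larger in size in excitatory neurons for 73 of the 106 and in inhibitory neurons for 33. By gene, neither class had the larger difference more often (187 of 355 larger in Emx1-Cre, exact binomial p = 0.339).

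**Figure D2:**
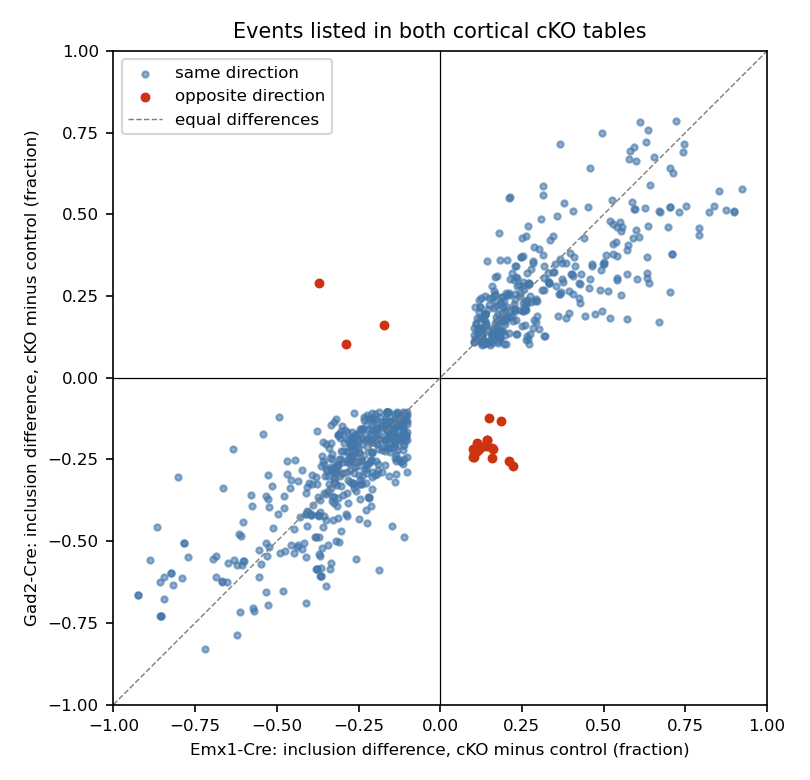
Inclusion difference, cKO minus control, as a fraction, of each of the 823 events listed in both cortical tables, in Emx1-Cre (horizontal) and Gad2-Cre neurons (vertical). Each point is 1 event and has no replicate error; 802 points share a direction and 21, in red, have opposite directions, and the empty band around 0 is the authors' threshold of 0.1.

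Excitatory and inhibitory neurons also differed from each other before any loss of Nova2. In Nin, a centrosomal protein gene, an exon of 411 nt on chromosome 12 from 70111072 to 70111482 had a level of 0.153 in excitatory and 0.833 in inhibitory controls in the authors' deposited table. Inhibitory controls also used more of a 69 nt exon of Exoc7, an exocyst subunit (0.183 against 0.842), and of a 21 nt coding exon of Trrap, on chromosome 5 from 144810332 to 144810352 (0.278 against 0.891), both the authors' values. Tandem exons of Csmd3 (0.427 against 1) and retained introns of the kinesin gene Kifc2 (0.170 against 0.8) and of Mroh1 (0.296 against 0.867) were higher there too, again by the authors' values.

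Excitatory controls had more of a 3' splice site isoform of Qk, the RNA-binding protein quaking, at 0.754 against 0.132 in the authors' deposited table. They also had more of the tandem exons of the receptor phosphatase Ptprd (0.668 against 0.129), of a 189 nt exon of Wdr45 (0.6 against 0.0811) and of a retained intron of the ribosomal protein gene Rps24 (0.893 against 0.387), all the authors' values. The exon of Uggt2 stood at 0.861 against 0.356 in the authors' deposited table in its longer form of 152 nt, and an exon at the locus of 2610203C20Rik at 0.807 against 0.333. Of 36 markers of other cell types, 1 was listed, Sox2, through events whose label also names the overlapping Sox2ot, with 0.426 against 0.124 by the authors' value.

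Of the gene lists, the cytoskeleton list had 14 genes in this table, of which 11 were higher in inhibitory and 3 in excitatory controls; a 22 nt exon of the microtubule gene Clasp2 stood at 0.277 in excitatory and 0.816 in inhibitory controls by the authors' value. The presynaptic list had 11 genes, 7 higher in inhibitory controls and 4 lower, and the adhesion list 10, with 6 higher and 4 lower. The RNA-binding list had 14, with 5 higher and 9 lower, among the latter Qk and Celf1. The glutamate synapse list had 6, with 4 higher and 2 lower; the ion channel list 5, with 4 higher and 1 lower; the axon guidance list 6, with 1 higher and 5 lower. The inhibitory synapse list had 2, Erbb4 higher and Gphn lower in inhibitory controls. The earlier NOVA targets had 8, with 3 higher and 5 lower. Over the table, 787 of 1236 events were higher in inhibitory controls (63.7%, exact binomial p = 5.11e-22, adjusted 4.6e-21), as were 323 of 534 cassettes (60.5%, p = 1.43e-06, adjusted 2.58e-06) and 95 of 112 retained introns (84.8%, p = 2.51e-14, adjusted 1.13e-13).

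Many of the events that set the classes apart changed again when Nova2 was lost, most of them toward the level of the other class. The Adgrl3 exon, at 0.439 in excitatory and 0.798 in inhibitory controls, moved toward the other class in both cKO groups by the authors' values, as did the Uggt2 exon. The table of controls shared 307 events in 165 genes with the Emx1-Cre cKO table, and 238 of them (77.5%) moved toward the inhibitory control level in the excitatory cKO (Fisher's exact test of direction against direction, p = 2.38e-20, adjusted 2.86e-20). It shared 323 events in 158 genes with the Gad2-Cre cKO table, and 303 of them (93.8%) moved toward the excitatory control level (Fisher's exact test, p = 1.36e-56, adjusted 4.08e-56). Exchanging values among events of like control level gave 59.9% and 65.7% toward. The share was higher in the inhibitory cKO by 16.3 percentage points (Fisher's exact test, p = 2.68e-09). With 1 shared event per gene it was 91.8% against 78.8% (Fisher's exact test, p = 0.00101), and with events matched by gene the gap was 8.29 points, 76.5% against 68.2% (p = 0.0493).

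Each of these pairs of tables used the same control libraries, and chance values of a control move an event toward the other class. In simulated tables with no effect, 2.63 events per draw were listed in both the control and the Emx1-Cre tables. For the control and the Gad2-Cre tables the number was 1.80, and in both pairs 100% of such events moved toward. The draws covered only the 3611 and 2883 events already listed, with the coverage taken as the count and counting error as the only spread. They therefore show the direction that chance values give, but not how many shared events are due to chance. The number expected for independent lists was not computed, because the events that were tested but not listed were not used here, and the controls could not be split, because only pooled levels are given. Part of the excess may therefore come from the shared controls.

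In the 107 events listed in all of the cortical tables, 88 changed in the same direction in both cKO groups. Of these, 68 moved the inhibitory cKO toward the excitatory control level, and 20 moved the excitatory cKO toward the inhibitory control level (exact binomial p = 2.77e-07; 34 of 49 with 1 event per gene, p = 0.0094). The other 19 had opposite directions, and in all 19 each class moved toward the other.

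**Figure D3:**
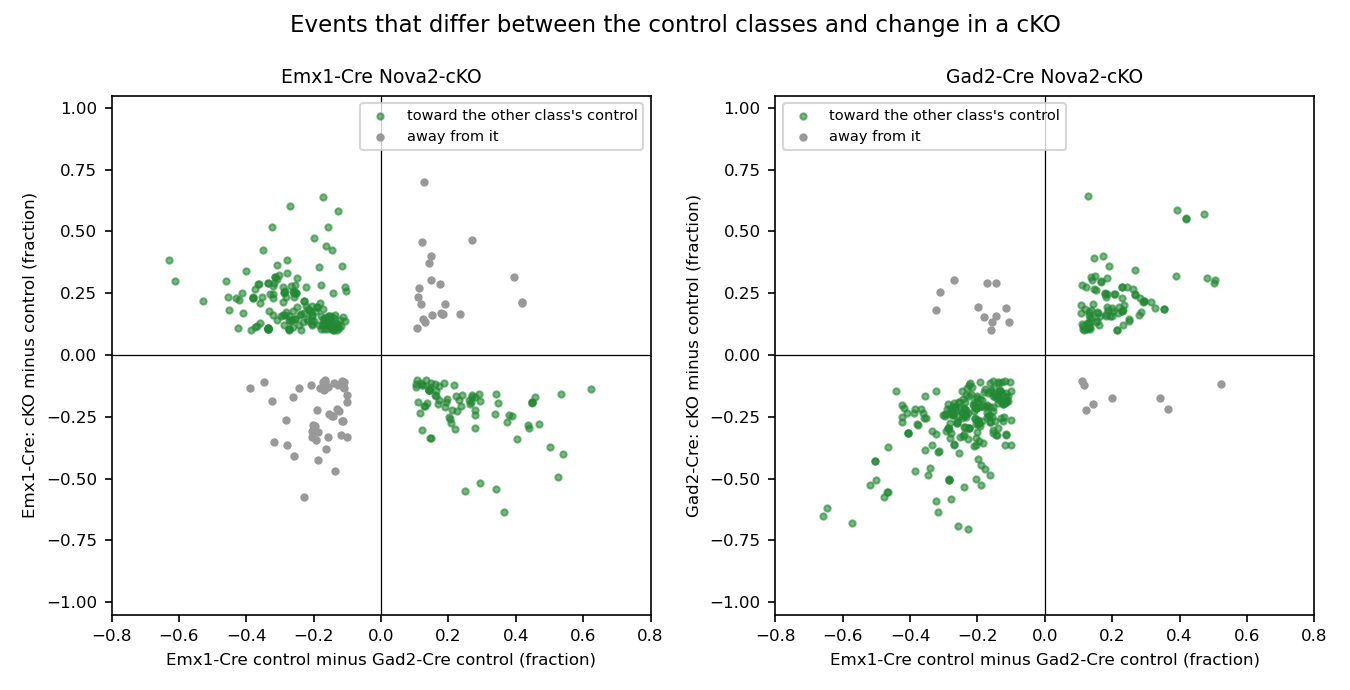
Inclusion difference between Emx1-Cre and Gad2-Cre controls (horizontal, fraction) against the difference of cKO minus control (vertical, fraction) for events listed in both tables, for the Emx1-Cre cKO (left, 307 events) and the Gad2-Cre cKO (right, 323 events). Green points, 238 on the left and 303 on the right, moved toward the control level of the other class and grey points away from it; each point is 1 event and has no replicate error.

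The Purkinje table names its groups only 1 and 2, and which of them is the control is not given in the sources used here, so directions are those of group 2 against group 1. A coding exon of 276 nt in Arhgap26, on chromosome 18 from 39357553 to 39357828, stood at 0.0585 in group 1 and 0.743 in group 2 of the authors' deposited table. Syt7, a calcium sensor of vesicle release, had an exon at 0.346 and 0.940 and a first-named mutually exclusive isoform at 0.489 and 0.0378, both the authors' values. Tandem exons of Gphn stood at 0.122 and 0.676, an exon of Sh3pxd2a at 0.391 and 0.880, and one of Cyb561 at 0.307 and 0.724, again the authors' values.

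Higher in group 1 was a 66 nt coding exon of the ephrin receptor Epha5, on chromosome 5 from 84117561 to 84117626, at 0.837 against 0.0909 in the authors' deposited table. A 24 nt coding exon of Ank1 (0.995 against 0.489), an exon of the microtubule gene Map7d2 (0.907 against 0.453), one of Ccdc85a (0.766 against 0.243) and a 45 nt form of the Ccdc64 exon (0.760 against 0.306) were higher there too by the authors' values. By list, 11 cytoskeleton genes were in the table, 4 higher in group 2 and 7 lower, and 9 RNA-binding genes, 8 higher and 1 lower, such as retained introns of Rbm25 (0.505 and 0.792) and Srsf6 (0.374 and 0.637), the authors' values. All 6 presynaptic genes were higher in group 2. There were 7 glutamate synapse genes, 4 higher and 3 lower, with an exon of Grm7 at 0.737 and 0.313 by the authors' value. There were 6 adhesion genes, 3 in each direction, 5 ion channel genes, 4 higher and 1 lower, 2 axon guidance genes, 1 in each direction, and 1 inhibitory synapse gene, Gphn, higher. The earlier NOVA targets had 7 genes, 4 higher and 3 lower. The markers of other cell types, a list that also holds the Purkinje cell genes Pcp2 and Calb1, had 0.

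Group 2 of the Purkinje table had the higher level in 409 of 603 events (67.8%, exact binomial p = 1.26e-18, adjusted 5.66e-18), in 189 of 268 cassettes (70.5%, p = 1.44e-11, adjusted 3.24e-11) and in 78 of 82 retained introns (95.1%, p = 7.61e-19, adjusted 5.66e-18). The Purkinje table shared 161 events in 69 genes with the Emx1-Cre table, 156 with the same sign of group 1 minus group 2 (96.9%, Fisher's exact test, p = 6.38e-34, adjusted 9.58e-34). Values exchanged among events of like level in Purkinje group 1 gave 81.2%. With the Gad2-Cre table it shared 147 events in 60 genes, 141 with the same sign (95.9%, Fisher's exact test, p = 5.62e-35, adjusted 1.12e-34), where exchanged values gave 76.4%. Across these events, which are not independent replicates, Pearson's r was 0.759 and Spearman's rho 0.720 with the Emx1-Cre table, and 0.848 and 0.773 with the Gad2-Cre table (permutation p = 0.0001 for each, the smallest they can give, adjusted 0.00012). With the table of cortical controls it shared 31 events, 18 with the same sign (58.1%, Fisher's exact test, p = 1).

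Retained introns made up 11.1% of the Emx1-Cre, 12.3% of the Gad2-Cre and 13.6% of the Purkinje table and 9.06% of the table of controls. Of 5 pairs of tables, only the controls against the Gad2-Cre cKO passed the test (odds ratio 0.712, Fisher's exact test, p = 0.00454, adjusted 0.0227). Among differences of at least 0.2 that odds ratio was 1.19, on the other side of 1. By the same test the adjusted p was 0.145 with 1 event per gene and 0.0637 at a coverage of at least 50. At an FDR of at most 0.01, the Purkinje against the Gad2-Cre table turned from an odds ratio of 1.12 to 0.612 and passed (Fisher's exact test, adjusted p = 0.0276), as did the controls against the Emx1-Cre table at 0.675 (adjusted p = 0.0276). Apart from any knockout, 95 of 112 listed introns were retained more in inhibitory than in excitatory controls.

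NOVA proteins bind RNA at clusters of YCAY, where Y is C or U, and binding within an exon is known to favour its skipping. Exons higher in the cKO held more of the motif in both cortical tables. These tables share 304 cassette exons, so their results are not independent of each other. Per 100 nt of exon, exons higher in the Emx1-Cre cKO held 2.02 ± 2.10 copies (SD, 337 exons) and exons lower in it 1.53 ± 1.62 (373 exons; two-sided permutation p = 0.00051, adjusted over the 3 tests 0.000765). The Emx1-Cre difference of 0.493 was 0.836 among exons that changed by at least 0.2. In the Gad2-Cre table the means were 2.32 ± 2.18 (220 exons) and 1.44 ± 1.55 (350 exons; permutation p = 1e-05, the smallest they can give, adjusted 3e-05). In the Purkinje table exons higher in group 2 held 1.55 ± 1.70 (155 exons) and exons higher in group 1 held 1.36 ± 1.45 (65 exons; permutation p = 0.41), a difference that did not pass the test. Against 229 cassette exons that differed only between controls, which held 1.73 ± 1.81, the exons higher in the Gad2-Cre cKO held more (permutation p = 0.0018, adjusted over 6 tests 0.0108), and the others did not pass. Introns were not searched, because no genome sequence was used here.

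The gene lists showed no difference between tables that passed the test. In 40 Fisher's exact tests of the number of listed genes between tables, 0 passed after adjustment (lowest adjusted p = 0.754), and 0 had an unadjusted p under 0.05 (lowest p = 0.127). Genes in both tables count on both sides, so these tests could miss a difference.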

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

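The comparisons of directions and of single events between tables were added after the tables had been seen, and the tests with 1 cassette event per gene, of introns that fell in both cortical tables and of Gad2-Cre control chance were chosen after the result was seen.

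Several events were listed with opposite directions in excitatory and inhibitory neurons. The test of the difference takes its spread from the authors' p-values, so its outcome is largely fixed for events that passed the authors' thresholds in opposite directions, and it adds no support of its own. As control minus cKO in Emx1-Cre minus the same in Gad2-Cre neurons, the difference was 0.662 for the Uggt2 exon, -0.492 for the Tmem214 intron and 0.389 for the Zfp516 isoform. For Adgrl3 it was -0.466 for the 18 nt exon and -0.405 and -0.38 for tandem forms that contain it, so these 3 events overlap. The share of listed tandem cassettes that were lower in cKO was 17.2 percentage points higher in Gad2-Cre (294 of 426) than in Emx1-Cre neurons (368 of 710; Fisher's exact test, p = 1.4e-08).

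The share of listed cassettes that fell was 10.7 percentage points higher in the Gad2-Cre than in the Emx1-Cre cKO (Fisher's exact test, p = 1.46e-05), with about as many falling (463 and 484) and fewer rising (263 and 428). Several events per gene were not the whole cause, as Fisher's exact test with 1 event per gene still gave p = 0.00199. A difference in coverage was not either: permuting the tables only among events in 5 classes of like coverage left a difference of 11.2 points (permutation p = 0.0001, the smallest they can give). Nor was a difference in control level, which left 7.1 points (permutation p = 0.001). The 320 cassettes listed in both tables count on both sides of these tests. Of them, 199 fell in Emx1-Cre and 201 in Gad2-Cre neurons, so the difference lies in cassettes listed in 1 table only (285 of 592 and 262 of 406 fell). The class of neuron remains as a hypothesis, and the purity of each sort was not tested.

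Retained introns were mostly higher in cKO, and lower in 11 percentage points more of the Gad2-Cre than of the Emx1-Cre events (Fisher's exact test, p = 0.00194). If more unspliced RNA in all genes of the cKO libraries were the whole cause, the 15.8% and 26.9% of introns that fell would be errors, unrelated between the cortical tables, which share no libraries. Of 83 introns listed in both, 1 per gene, 10 fell in Emx1-Cre and 13 in Gad2-Cre neurons, and 10 in both (Fisher's exact test of direction against direction, p = 1.18e-10). This argues against more unspliced RNA as the whole cause of the intron changes there. However, a like control level can also tie directions, and it was not held fixed in that test. More unspliced RNA may still be the cause of the rise in the introns that rose. Of Purkinje introns, 4.88% were lower in group 2 (4 of 82), too few for that test, and the explanation stays open. Retention was also higher in inhibitory than in excitatory controls for 95 of 112 introns, with no knockout involved. Of 35 introns listed both between controls and in the Gad2-Cre table, 30 were higher in inhibitory controls, and only 6 rose in the Gad2-Cre cKO. Of 44 listed both between controls and in the Emx1-Cre table, 37 rose in the Emx1-Cre cKO. The difference of 11 points may therefore rest on the Gad2-Cre control values, which was not tested.

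Events that differ between the control classes moved toward the other class in 16.3 percentage points more of the Gad2-Cre than of the Emx1-Cre cKO events, and in 8.29 points more with events matched by gene (Fisher's exact test, p = 0.0493). Of 87 such Gad2-Cre events listed also in the Emx1-Cre cKO, 68 moved the same way there (78.2%), and for the Emx1-Cre part 20 of 39 did so in the Gad2-Cre cKO (51.3%). A cKO effect common to both classes gives the same direction whatever made the controls differ (88 of the 107 events in all of these tables had it), so neither share decides, and chance values of the Gad2-Cre and of the Emx1-Cre controls both stay open where they add to real effects. Several events per gene were excluded as the whole cause, as Fisher's exact test with 1 shared event per gene gave p = 0.00101. The class of neuron stays open as well and was not tested apart from the shared controls; levels per library, with other control libraries in each table, would decide between them.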

How the results depend on the processing

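The values with YCAY in exons equal to a GENCODE exon or of at least 20 nt, and all those of exon length, were chosen after the result was seen; the rest were planned. Of 107 alternative values of 22 results, 91 kept their direction and their side of the threshold, 3 lost the call, 3 gained it and 10 turned; the cause was not tested. Over all alternatives, the share of shared cortical cKO events with the same direction lay between 84.5% and 99.5%, both Purkinje shares between 71.4% and 100%, and the YCAY difference between 0.442 and 0.836 in Emx1-Cre and between 0.805 and 1.31 in Gad2-Cre exons. The share of events lower in cKO became 53.3% in Emx1-Cre neurons with differences of at least 0.2 and 48.9% with 1 event per gene, where it became 51.9% in Gad2-Cre neurons. By exact binomial tests the 53.3% passed (p = 0.014, against 0.109 in the main setting) and the 51.9% did not (p = 0.28). With 1 event per gene the retained intron odds ratios were 1.03 for Emx1-Cre against Gad2-Cre and 0.764 for controls against Gad2-Cre. With differences of at least 0.2 they were 0.933 for Purkinje against Gad2-Cre, and 1.43 and 1.19 for controls against Emx1-Cre and Gad2-Cre. At an FDR of at most 0.01 they were 0.721 and 0.612 for Purkinje against Emx1-Cre and Gad2-Cre, and 0.675 for controls against Emx1-Cre; the 0.612, though turned, passed the test (adjusted p = 0.0276), as did the 0.675 (adjusted p = 0.0276). At a coverage of at least 50 they were 0.943 and 0.874 for Purkinje against Emx1-Cre and Gad2-Cre, and 0.689 for controls against Gad2-Cre. The 0.689 no longer passed (Fisher's exact test, adjusted p = 0.0637). The YCAY difference in Purkinje exons was -0.129 per 100 nt with differences of at least 0.2. With 1 exon per gene, coding exons of a multiple of 3 nt were 14.1 points more frequent among shared than among Emx1-Cre-only exons, which passed (Fisher's exact test, adjusted p = 0.0089), against 8.47 points over all exons (adjusted p = 0.0519). The gene lists gave 0 calls of 40 also with differences of at least 0.2 and with cassettes only. No paired analysis was possible because the tables hold 1 pooled value per group; leaving out replicates was not run for the same reason. The YCAY window of 100 nt was not run because introns were not searched. Events at a coverage near 20 have the least certain levels.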

Other observations

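The tests of YCAY order and of the control position were set down before their results were seen, whereas those of exon length and reading frame and of the Purkinje group order were chosen after results were seen.

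Cassette exons that changed in both classes of cortical neuron were more often a multiple of 3 nt long than those listed in 1 class, though for coding exons not past the threshold against excitatory neurons over all exons. Of 304 shared exons, 196 were (64.5%), against 305 of 562 listed in excitatory neurons only (54.3%, Fisher's exact test, p = 0.00393, adjusted over 6 tests 0.0059) and 183 of 395 listed in inhibitory neurons only (46.3%, p = 1.97e-06, adjusted 1.18e-05). Within coding sequence, 152 of 198 shared exons were (76.8%), against 209 of 306 (68.3%, Fisher's exact test, p = 0.0432, adjusted 0.0519) and 110 of 198 (55.6%, p = 1.19e-05, adjusted 3.57e-05). So the former comparison did not pass; with 1 exon per gene both did, 82.1% against 67.9% (Fisher's exact test, adjusted p = 0.0089) and 78.8% against 58.2% (adjusted p = 0.00488). Microexons of at most 27 nt made up 29 of the 304 shared exons (9.54%). They made up 42 of 562 of the excitatory-only exons (7.47%, Fisher's exact test, adjusted p = 0.301) and 14 of 395 of the inhibitory-only exons (3.54%, adjusted p = 0.00266). The same 304 exons serve in both comparisons. Shared cassette events were better covered, with a median of 89.8 against 46 in the Emx1-Cre and 70.5 against 39 in the Gad2-Cre table. Neither coverage nor the size of the difference was held fixed here.

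Between the controls, microexons were more frequent among exons that inhibitory neurons used more, 47 of 318 (14.8%), than among those that excitatory neurons used more, 14 of 208 (6.73%; Fisher's exact test, p = 0.00509, adjusted over 12 tests 0.0306). The Trrap exon of 21 nt and the Clasp2 exon of 22 nt belong to the former. With 1 exon per gene the counts were 30 of 204 and 9 of 128 (Fisher's exact test, p = 0.0365, adjusted 0.146), so this did not pass by gene. Over all exons, coding exons used more by inhibitory neurons were also more often a multiple of 3 nt, 120 of 162 (74.1%) against 67 of 129 (51.9%, Fisher's exact test, p = 0.000126, adjusted 0.00151), and with 1 exon per gene 75.0% against 58.1% (p = 0.0224, adjusted 0.134), so this did not pass by gene either. In the Emx1-Cre cKO table, coding exons that rose were a multiple of 3 nt in 68.1% and those that fell in 74.8% (Fisher's exact test, adjusted p = 0.339), which did not pass, but with 1 exon per gene the shares were 65.8% and 80.9%, which did (98 of 149 and 123 of 152, Fisher's exact test, p = 0.00395, adjusted over 12 tests 0.0474).

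One hypothesis is that group 1 of the Purkinje table is the control. The share of events with the same sign as in the Emx1-Cre table, whose group 1 is the control, was 96.9% (156 of 161, 95% interval from 92.9% to 99%), and 141 of 147 had the sign of the Gad2-Cre table. This is in line with that order, under which 78 of 82 Purkinje introns would be retained more in the cKO, but it assumes that the same events respond alike in both tissues.

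A second hypothesis concerned the YCAY difference, which might come from base composition alone. The other 11 orders of the same 4 bases differed less: YCAY ranked 1 of 12 in both cortical tables. The largest difference of another order was 0.4 against 0.493 for YCAY in Emx1-Cre exons, and 0.519 against 0.873 in Gad2-Cre exons. The excess of YCAY over the mean of the other orders was 0.29 per 100 nt in Emx1-Cre exons (permutation p = 0.0045). In Gad2-Cre exons it was 0.633 (permutation p = 1e-05, the smallest they can give). These values argue against the composition of single bases as the whole cause. The cortical tables share exons, so their results are not independent. Other sequence features of these exons, such as pairs of adjacent bases, were not tested.

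Another hypothesis was that inhibitory controls lie farther from the knockout state. Over shared events with the same direction, 1 per gene, the Gad2-Cre control level lay farther on the control side than the Emx1-Cre level in 209 of 346 genes (60.4%, 95% interval from 55% to 65.6%, exact binomial p = 0.000128). The mean shift was 0.0261 ± 0.105 (SD). The Gad2-Cre cKO level lay to the same side in 234 genes, and its mean shift over all of these genes was 0.0397 ± 0.101. As that mean shift was the larger one, inhibitory controls did not on average lie farther from their own cKO level than excitatory controls did. The control values alone go with a level farther out in inhibitory neurons. As the cKO level lay to the same side, they do not separate this from a shift of inhibitory neurons that is independent of Nova2.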
